A study of Medicago truncatula with 15 samples.

How the data were processed

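RNA was sequenced from leaves of Medicago truncatula (barrel medic) receiver plants that grew beside a sender plant, with 15 libraries in 4 groups. Per the labels, a sender was treated with water (H2O) or with WF, and the common mycelial network, the fungal threads that link the roots of neighbouring plants, was left connected or was cut. The legend deposited with the tables gives WF as wounding of the sender together with flg22, a peptide of bacterial flagellin that plants sense as a sign of bacteria. The groups held 4 H2O connected, 4 H2O cut, 4 WF connected and 3 WF cut libraries, each from a plant of its own per the labels' protocols. Those protocols describe receivers of 8 weeks, 3 trifoliate leaves per plant, 400 ng of RNA per library, depletion of ribosomal RNA and strand-specific libraries.

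The values used here are the authors' own comparisons. The deposited tables give, per gene, the authors' log2 fold change of WF over H2O and the authors' FDR (an adjusted p-value), for the connected network and for the cut network. Each value belongs to a comparison of groups and none to a single plant. The submitters' processing notes name fastp 0.20.0, STAR 2.7.10a and limma, without saying what each did. The library scaling, the filter on low counts and the number of genes tested are not given in the sources used here. Gene models are those of MtrunR108_HiC, the R108 genome build, per the file headers, and positions are given as the scaffold in the deposited locus tags. Gene coordinates were not used here, since the reference table supplied for names is of another build.

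The tables were checked for what they hold. The highest FDR was 0.05 in both comparisons, so the tables hold genes past that threshold alone. They list 32377 genes, which is 83.0% of the gene numbers up to the highest listed, 39012. One table holds 21809 genes past the threshold in both comparisons with the same sign, another 4885 genes of the connected comparison and another 5698 genes of the cut comparison. A further table of 15 genes repeats those found in both of the latter tables, whose signs differ, with identical values. A gene that is not listed for a comparison may have missed the threshold or may not have been tested, and these cannot be separated here.

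The plan written before the data were examined foresaw tests on values per library, and, where no such values were given, a description of the authors' fold changes. That second course was taken. The interaction of treatment with network, connected against cut within a treatment, other scalings, other filters, the replicate block, leaving out libraries and other splits of the libraries need values per library and were not analysed here. Depth per library is unknown here, so no value could be weighted by depth. No standard errors came with the fold changes, and the SD between plants is unknown here. The authors' FDR is therefore the only measure of error available for the fold changes. It is printed beside some of them, and many are printed without it. Those without it are known only to be past the FDR threshold of the deposited tables.

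Genes were grouped into 38 lists by words in the 2 deposited description columns, with the words fixed before the data were examined. The columns were joined for matching, so words in different columns could meet a list's terms together. This admitted 99 of 202 genes of the protease inhibitor list and 30 of 689 receptor-like kinases, was noticed after the results were seen, and is followed up beside those lists. Words also bring in genes of related families, such as histone methyltransferases under histones. For 9 lists, genes whose descriptions name another family were taken out in an alternative whose terms were set after the main results were seen. Other lists were not narrowed in this way. For each list, the split of its listed members into higher and lower was compared with that of the other listed genes in the same comparison by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 38 lists. This test replaces the list test first foreseen, which needs values per library. It says whether a list leans to one side more than other listed genes do. Genes are not independent replicates, and the correlation between genes could not be estimated, so these p-values are too small to an unknown degree. Another pair of tests, chosen after the data were seen, was two-sided. It asked which lists had more or fewer genes lower with the connected network that were not listed as lower with the cut network. It asked the same for genes higher with the cut network that were not listed as higher with the connected network. A further 12 lists were chosen after the data were seen and are described in the closing part, with adjustment over those 12.

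Named genes were taken by a rule fixed before the data were examined: per comparison, the 10 higher and 10 lower genes with the smallest FDR and an informative description, and per list with at least 3 listed members the 2 higher and 2 lower members with the smallest FDR. Genes of a deposited list of up to 50 genes could be named too, which admits the 15 genes of opposite sign. The rule's minimum on expression could not be applied, and ties in FDR were broken by the larger fold change, a choice made after the data were seen. Set before the data were examined was 1 other setting, a minimum absolute log2 fold change of 1. Added after the data were seen were an FDR threshold of 0.01, list membership by either description column alone, membership with all words within 1 column, and the narrowed lists.

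The list test was tested on simulated data with lists of a known odds ratio of 4. It recovered 97.5% of the changed lists among the 26694 genes of the connected comparison and 98.3% among the 27507 genes of the cut comparison. Of unchanged lists, 3.5% and 4.1% had an unadjusted p under 0.05. These simulated genes were independent of one another. The changed lists were drawn from the larger lists alone and at that odds ratio alone. Recovery of smaller lists or of weaker leans was therefore not tested. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.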

Results

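Transcripts were measured by RNA sequencing in leaves of Medicago truncatula plants, called receivers, whose neighbour, the sender, had been treated with water (H2O) or with WF (wounding plus the flagellin peptide flg22). The common mycelial network between the plants was connected or cut. There were 4 libraries each of H2O connected, H2O cut and WF connected receivers and 3 of WF cut receivers. The depth of each library is unknown here, since the tables hold the authors' log2 fold changes and FDRs and no values per plant. The comparisons asked how receiver leaves differed after treatment of the sender, with the network connected and with it cut. Of these 2 comparisons, neither shares a library with the other.

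Receiver leaves of WF-treated senders differed from those of water-treated senders in most annotated genes, and genes of photosynthesis were lower with either state of the network. Whether this breadth lies in the plants or in a technical difference of the WF libraries is open and is taken up in the closing part. With the connected network 26694 genes were listed, 15131 higher and 11563 lower. With the cut network 27507 were listed, 18368 higher and 9139 lower. The share that was higher was 56.7% with the connected and 66.8% with the cut network. The median listed higher gene stood 2.71-fold higher with the connected and 5.27-fold higher with the cut network, and the median listed lower gene stood 3.54-fold and 3.13-fold lower. At an FDR of 0.01 lower genes outnumbered higher ones with the connected network, 10087 against 7934 (44.0% higher), so its excess of higher genes depends on the threshold. With the cut network 12446 were higher and 3832 lower at that FDR (76.5% higher).

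The comparisons shared 21809 genes with the same sign, 13251 higher and 8558 lower, and 15 genes with opposite signs. Independent lists over 39012 genes, the highest gene number and an assumed total, would share 7124 higher and 2709 lower genes and hold 8989 genes of opposite sign. The 4870 other genes of the connected comparison were 1877 higher and 2993 lower, and the 5683 others of the cut comparison were 5105 higher and 578 lower. These counts depend on the threshold. At an FDR of 0.01, 8851 genes were shared with the same sign. In the connected comparison alone were 9167, of them 6664 lower, and 7424 in the cut comparison alone, 7014 of them higher. Across the genes listed in both, which are not independent replicates, Pearson's r was 0.94 and Spearman's rho 0.83. Among genes higher in both r was 0.32 and rho 0.34, and among genes lower in both they were 0.70 and 0.73. Of the genes higher in both, 12359 (93.3%) had the larger fold change with the cut network, with medians of 2.42 against 1.44 on the log2 scale. Of those lower in both, 6127 had the larger fold change with the connected network, with medians of -1.96 against -1.68. Whether a gene's fold change differed between the comparisons was not tested, since no standard errors were given.

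**Figure D1:**
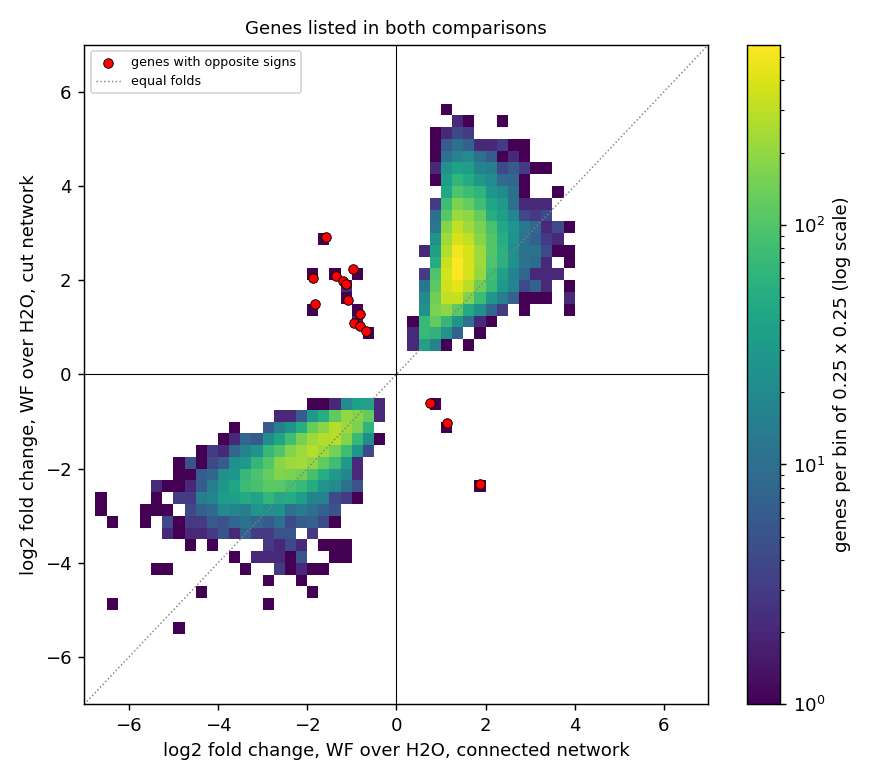
Authors' log2 fold changes (WF over H2O) of genes listed in both comparisons, connected network on the x axis and cut network on the y axis, with the number of genes per bin in colour on a log scale. Most higher genes lie above the dotted line of equal folds, and the 15 red points have opposite signs.

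With the connected network, the genes of light capture and carbon fixation were lower, as were genes of protein synthesis and of the circadian clock. P450 enzymes, cell wall enzymes and markers of seeds, flowers, roots and nodules were higher in a larger share than the 56.7% of all listed genes. Of 82 listed photosystem and light-harvesting genes 78 were lower, with a median log2 fold change of -3.16 (Fisher's exact test, adjusted p = 2.8e-22). All 21 listed genes of the Calvin cycle list were lower, with a median of -3.97 (adjusted p = 2.2e-07), and so were all 16 left without members such as Rubisco methyltransferases. The Calvin cycle fixes carbon dioxide. In the authors' deposited table an LHCII chlorophyll a-b binding protein (MtrunR108HiC_025977, scaffold 6) stood at -6.26 (FDR 1.3e-05) and oxygen-evolving enhancer protein 1 (MtrunR108HiC_021923, scaffold 5), which helps to split water, at -2.90 (FDR 9.9e-06). Small chains of Rubisco, the enzyme that fixes carbon dioxide, stood at -5.47 (MtrunR108HiC_026323, scaffold 6) and -4.84 (MtrunR108HiC_028855, scaffold 7) in the authors' deposited table. Among the 4 higher members of the photosystem list were chlorophyll a-b binding protein 8 (MtrunR108HiC_025552, scaffold 5), at 1.50, and a photosystem II 32 kDa protein (MtrunR108HiC_015733, scaffold 4), at 1.90, in the authors' deposited table.

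Genes for proteins of the cytosolic ribosome were 153 lower and 43 higher with the connected network (adjusted p = 7e-22), or 152 and 35 without ribosome export proteins. The authors' deposited table held 60S protein L18a (MtrunR108HiC_009684, scaffold 2) at -3.45 and the ubiquitin fusion of 40S protein S27a (MtrunR108HiC_022707, scaffold 5) at -3.50. On the other side, 40S protein S15-4 (MtrunR108HiC_018447, scaffold 4) stood at 3.43 in the authors' deposited table. Of 20 listed circadian clock genes 17 were lower (adjusted p = 0.0008), among them EARLY FLOWERING 3 (MtrunR108HiC_000427, scaffold 1), part of the evening complex, at -2.42 and REVEILLE 6 (MtrunR108HiC_027198, scaffold 6) at -2.41 in the authors' deposited table.

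Several further lists, of defence and of other functions, leaned lower with the connected network. The general phenylpropanoid enzymes, which open the path to lignin and flavonoids, were 32 lower and 16 higher (adjusted p = 0.0052). Phenylalanine ammonia-lyase, the entry enzyme, stood at -3.19 (MtrunR108HiC_032679, scaffold 7) and -4.58 (MtrunR108HiC_002780, scaffold 1) in the authors' deposited table. Calcium signalling genes were 84 lower and 69 higher (adjusted p = 0.011), with a calcium-dependent protein kinase (MtrunR108HiC_011971, scaffold 3) at -3.66 and the calcium sensor CML42 (MtrunR108HiC_015108, scaffold 3) at 1.99 in the authors' deposited table. The phosphate list was 65 lower and 47 higher (adjusted p = 0.0072), but 50 of its 129 members, mostly sugar phosphate transporters and kinases, belong to other families. Without them it was 38 and 33 and did not lean past the threshold (adjusted p = 0.18), with an odds ratio of 0.66 (95% interval 0.40 to 1.09) against 0.55 (0.37 to 0.82). Phosphate transporter genes with consecutive numbers stood at -4.27 (MtrunR108HiC_003272, scaffold 1) and 2.37 (MtrunR108HiC_003273, scaffold 1) in the authors' deposited table. Glutathione S-transferases were 35 lower and 23 higher (adjusted p = 0.027), and genes of abscisic acid and dehydration 61 lower and 50 higher (adjusted p = 0.033), with abscisic acid 8'-hydroxylase (MtrunR108HiC_022303, scaffold 5), which breaks the hormone down, at -2.71 in the authors' deposited table.

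The lists that leaned higher with the connected network included cytochrome P450 genes, 160 higher and 60 lower (adjusted p = 7.6e-06). P450 94C1-like (MtrunR108HiC_008088, scaffold 2) stood at 3.77 and P450 98A2 (MtrunR108HiC_031933, scaffold 7) at -2.82 in the authors' deposited table. Cell wall remodelling genes were 251 higher and 124 lower (adjusted p = 0.00027), with a pectate lyase (MtrunR108HiC_022812, scaffold 5) at 3.53 and a cellulose synthase subunit (MtrunR108HiC_020280, scaffold 4) at -4.16 in the authors' deposited table. Genes of ethylene synthesis and factors described as ethylene-responsive or ERF were 111 higher and 50 lower (adjusted p = 0.0068). These factors, AP2-like AIL6 among them, were matched by name, which does not show that they respond to ethylene. An ACC synthase (MtrunR108HiC_020593, scaffold 4), which makes the precursor of ethylene, stood on the other side at -3.68 in the authors' deposited table. NBS-LRR resistance genes were 219 higher and 125 lower (adjusted p = 0.022), protease inhibitors 107 higher and 49 lower (adjusted p = 0.0083), flavonoid enzymes 100 and 50 (adjusted p = 0.029) and genes with a lectin domain 88 and 43 (adjusted p = 0.033). Of the 167 members of that last list 149 belong to other families, mostly receptor kinases. The rest were 9 and 4 (adjusted p = 0.58), with an odds ratio of 1.72 (95% interval 0.48 to 7.6) against 1.57 (1.08 to 2.31) for the full list, so 13 genes leave open whether lectins leaned. Of the 202 members of the protease inhibitor list, 99 matched only by words in different description columns. With words required in 1 column the list held 51 higher and 31 lower genes and did not lean past the threshold (adjusted p = 0.5). The odds ratio was then 1.26 (0.79 to 2.04) against 1.67 (1.18 to 2.40), so whether protease inhibitors leaned is open. The 2 higher genes of that list with the smallest FDR had descriptions of pectinesterase inhibitors, which act on the cell wall and not on proteases. The higher flavonoid gene of smallest FDR (MtrunR108HiC_028952, scaffold 7), at 3.77 in the authors' deposited table, had a Copia-like retrotransposon protein as 1 of its descriptions. The flavonoid call ended with the minimum fold change and with the similarity column alone.

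Markers of seeds and flowers and of roots and nodules leaned higher as well. Seed and flower markers were 135 higher and 14 lower with the connected network (adjusted p = 1.6e-18) and root and nodule markers 66 and 26 (adjusted p = 0.011). Without leguminosin peptides the former were 103 and 10 (adjusted p = 1.4e-14). Without members such as CASP-like and early nodulin-like proteins the latter were 48 and 3 (adjusted p = 4.2e-08). The list of epidermis, wax and cutin genes, 121 and 42 (adjusted p = 2.3e-05), holds 135 GDSL lipases and stomatin-like genes among 204 members. Without them it was 36 and 23 and did not lean past the threshold (adjusted p = 0.73), with an odds ratio of 1.20 (95% interval 0.69 to 2.12) against 2.21 (1.54 to 3.22). Vascular markers, 21 and 14, did not lean past the threshold (adjusted p = 0.8). The authors' deposited table held the flower factor AGL80 (MtrunR108HiC_011234, scaffold 3) at 3.27 and a late nodulin (MtrunR108HiC_007550, scaffold 2), a gene class of root nodules, at 3.23.

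Several defence lists did not lean past the threshold with the connected network. Genes of jasmonate synthesis were 26 higher and 25 lower (adjusted p = 0.59), TIFY family genes 7 and 12 (adjusted p = 0.17), salicylate regulators 10 and 12 (adjusted p = 0.41), WRKY factors 40 and 45 (adjusted p = 0.14), pathogenesis-related proteins 34 and 24 (adjusted p = 0.84) and chitinases and glucanases 56 and 34 (adjusted p = 0.44). The TIFY list covers the JAZ repressors of jasmonate signalling, but 6 of its 22 members, mostly GATA factors, are not JAZ genes by their descriptions. The rest were 5 and 9 (adjusted p = 0.3). The absence of a lean depends on the settings. With a minimum fold change WRKY factors leaned lower (adjusted p = 0.037). TIFY genes (adjusted p = 0.027) and jasmonate synthesis (adjusted p = 0.046) did so at an FDR of 0.01. Single members still moved far: WRKY53 (MtrunR108HiC_034792, scaffold 8) stood at -4.51, an EDS1-like gene of salicylate defence (MtrunR108HiC_013364, scaffold 3) at -4.01 and a basic beta-1,3-glucanase (MtrunR108HiC_006894, scaffold 2) at -4.64 in the authors' deposited table. A WRKY70-like gene (MtrunR108HiC_008571, scaffold 2) stood at 3.14 in the authors' deposited table. The remaining lists, given as higher and lower genes, did not lean past the threshold either: receptor-like kinases 329 and 230 (adjusted p = 0.41), MAP kinases 18 and 27 (adjusted p = 0.064, or 0.01 with the minimum fold change), class III peroxidases 54 and 30 (adjusted p = 0.27), terpene enzymes 43 and 30 (adjusted p = 0.8) and UDP-glycosyltransferases 101 and 69 (adjusted p = 0.59). This held also for heat shock proteins, 71 and 75 (adjusted p = 0.098), nitrate genes, 45 and 38 (adjusted p = 0.76), sugar and starch genes, 57 and 50 (adjusted p = 0.59), and auxin response genes, 80 and 60 (adjusted p = 0.96). Senescence genes were 26 and 30 (adjusted p = 0.21, or 0.0094 with the reference description alone), carotenoid cleavage and strigolactone genes 6 and 4 (adjusted p = 1) and the histone list 73 and 41 (adjusted p = 0.2). By smallest FDR, the lower genes were led by a heavy-metal-associated isoprenylated protein (MtrunR108HiC_027204, scaffold 6) at -4.01 and CASP-like protein 4A3 (MtrunR108HiC_037536, scaffold 8) at -3.42, both with FDR 5.3e-06 in the authors' deposited table. Of the 19 lists that leaned past the threshold, 5 did so under every alternative: phenylpropanoid enzymes, P450, photosystems, Calvin cycle and cell wall. The other 14 lost the call or turned at an FDR of 0.01, with a minimum fold change or with other rules for membership. For some, among them ribosomal proteins, seed and flower markers and the clock, this came only with the reference description alone. That rule kept 8 of 215, 9 of 202 and 5 of 21 of their members, so these lists were hardly tested by it.

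**Figure D2:**
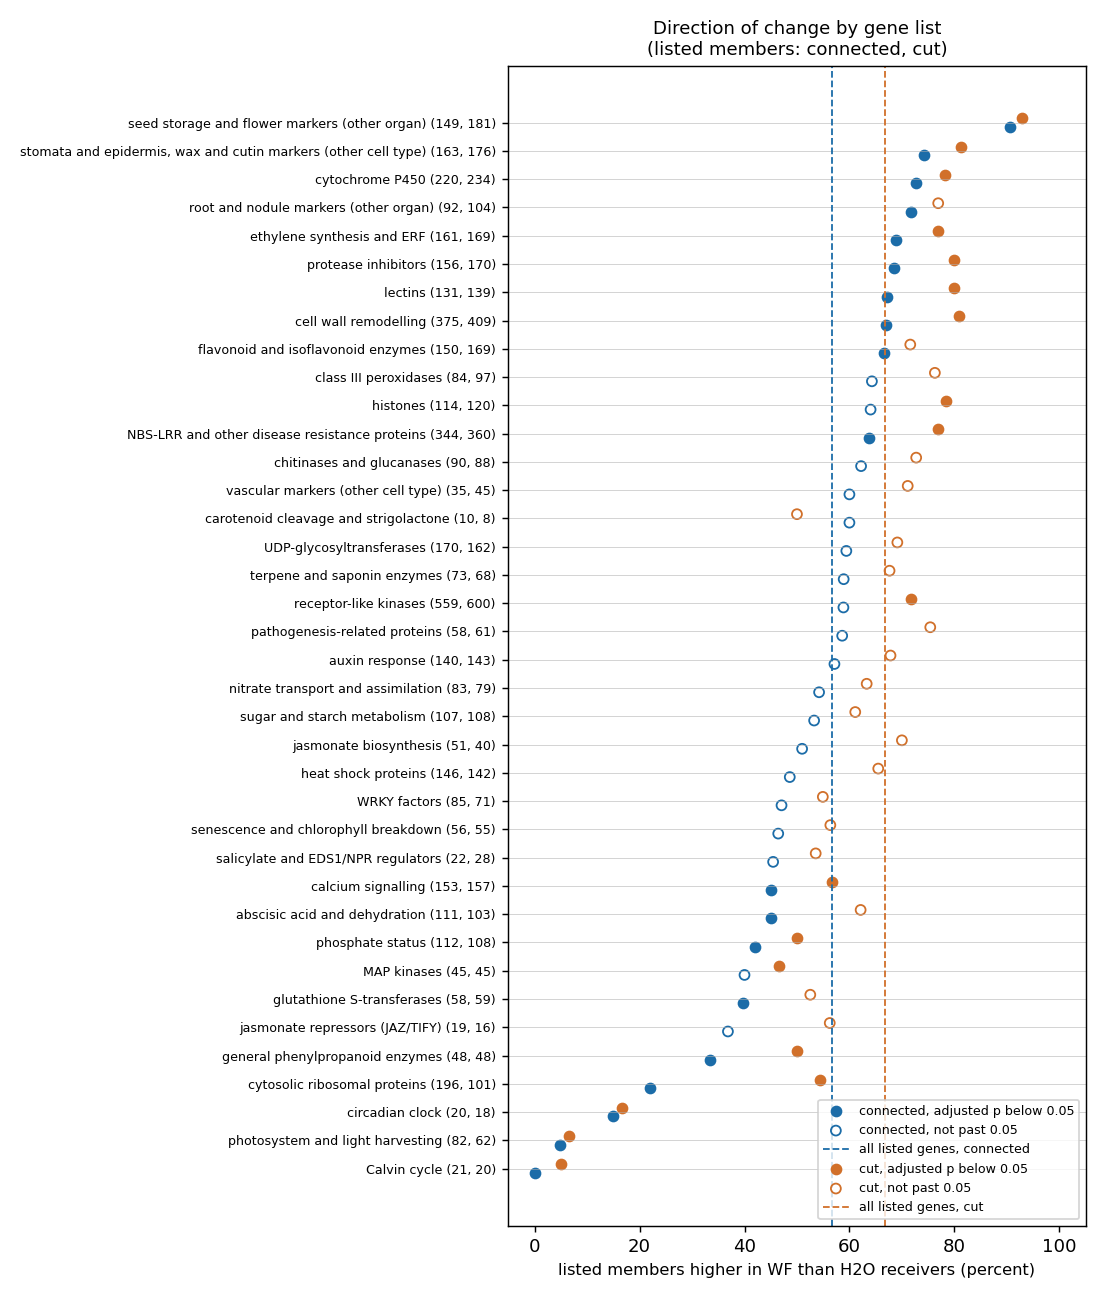
Share of listed members that were higher in WF than in H2O receivers, in percent, for 38 gene lists, with the connected network in blue and the cut network in orange. Filled points have an adjusted p below 0.05 by Fisher's exact test, and dashed lines give all listed genes, 56.7% and 66.8%.

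With the cut network, photosynthesis genes were again lower and genes of the cell wall, of resistance and of seeds and flowers mostly higher. The photosystem list had 58 lower and 4 higher genes, with a median of -2.30 (adjusted p = 6.8e-22), and the Calvin cycle list 19 lower and 1 higher, with a median of -2.51 (adjusted p = 1e-07). In the authors' deposited table cytochrome f (MtrunR108HiC_021071, scaffold 412) of the photosynthetic electron chain stood at -4.67 and a Rubisco activase-type gene (MtrunR108HiC_010112, scaffold 2) at -2.28. A Rubisco small chain gene (MtrunR108HiC_038596, scaffold 8) was the 1 higher Calvin cycle gene, at 1.56 (FDR 0.045) in the authors' deposited table. Circadian clock genes were 15 lower and 3 higher (adjusted p = 0.00013), with ELF4-LIKE 4 genes at -2.02 (MtrunR108HiC_007357, scaffold 2) and 2.44 (MtrunR108HiC_038474, scaffold 8) in the authors' deposited table.

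Cell wall genes were 331 higher and 78 lower with the cut network (adjusted p = 2.8e-09), NBS-LRR genes 277 and 83 (adjusted p = 0.00015), receptor-like kinases 430 and 170 (adjusted p = 0.023), P450 genes 183 and 51 (adjusted p = 0.00067), protease inhibitors 136 and 34 (adjusted p = 0.00067), the lectin domain list 111 and 28 (adjusted p = 0.0027), ethylene genes 130 and 39 (adjusted p = 0.016) and the histone list 94 and 26 (adjusted p = 0.017). The histone list holds 70 genes of other families, mostly histone methyltransferases, among its 146 members. Without them histones were 47 and 10 (adjusted p = 0.028). Without kinases and other families, lectins were 13 and 2 (adjusted p = 0.28), with an odds ratio of 3.24 (95% interval 0.73 to 29.5) against 1.98 (1.30 to 3.11) for the full list. The interval reaches below 1, so these few genes leave open whether lectins leaned. With words required in 1 description column, protease inhibitors were 58 and 19 (adjusted p = 0.19), without a lean past the threshold, and receptor-like kinases 410 and 164 (adjusted p = 0.042). In the authors' deposited table P450 71D11 (MtrunR108HiC_026783, scaffold 6) stood at 5.70, ethylene-responsive factor 1B (MtrunR108HiC_003007, scaffold 1) at 5.12, a WRKY70-like gene (MtrunR108HiC_008573, scaffold 2) at 5.13 and a disease resistance protein RGA1 (MtrunR108HiC_026275, scaffold 6) at 4.65. An isopentenyltransferase of cytokinin synthesis (MtrunR108HiC_010717, scaffold 3) stood at 4.58 and a mannose-specific lectin (MtrunR108HiC_036423, scaffold 8) at 4.83 in the authors' deposited table. Seed and flower markers were 168 higher and 13 lower (adjusted p = 1.2e-15) and the epidermis list 143 and 33 (adjusted p = 0.00015), which without GDSL lipases and stomatin-like genes was 43 and 16 (adjusted p = 0.53). Root and nodule markers, 80 and 24, had an adjusted p of 0.054. Without members such as CASP-like proteins they were 57 and 2 (adjusted p = 3.1e-07). The authors' deposited table held AGL62 (MtrunR108HiC_003405, scaffold 1), a factor of seed development, at 5.01 and a late nodulin (MtrunR108HiC_028066, scaffold 6) at 4.76.

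Lists that leaned lower relative to the other genes with the cut network were calcium signalling, 68 lower and 89 higher (adjusted p = 0.021), MAP kinases, 24 lower and 21 higher (adjusted p = 0.017), the phosphate list, 54 and 54 (adjusted p = 0.0012, or 0.053 without other families), phenylpropanoid enzymes, 24 and 24 (adjusted p = 0.043), and ribosomal proteins, 46 lower and 55 higher (adjusted p = 0.024). In these lists the share of higher genes lay under the 66.8% of all listed genes, and of the 5 lists MAP kinases alone had more lower than higher genes. The kinase MMK2 (MtrunR108HiC_020585, scaffold 4) stood at -2.87, phenylalanine ammonia-lyase (MtrunR108HiC_032679, scaffold 7) at -2.12 and an SPX-domain membrane protein gene (MtrunR108HiC_023370, scaffold 5) at -2.05 in the authors' deposited table. Higher members included calmodulin-like protein 7 (MtrunR108HiC_035125, scaffold 8) at 3.31 and phosphate transporter 1-4 (MtrunR108HiC_003006, scaffold 1) at 3.46 in the authors' deposited table.

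Jasmonate synthesis genes, 28 higher and 12 lower (adjusted p = 0.8), TIFY family genes, 9 and 7 (adjusted p = 0.54), WRKY factors, 39 and 32 (adjusted p = 0.077), pathogenesis-related proteins, 46 and 15 (adjusted p = 0.26), and chitinases and glucanases, 64 and 24 (adjusted p = 0.35), did not lean past the threshold with the cut network. WRKY factors did lean lower with the minimum fold change (adjusted p = 0.036) and at an FDR of 0.01 (adjusted p = 0.0047), and pathogenesis-related proteins leaned higher with the reference description alone (adjusted p = 0.028). Neither did flavonoid enzymes, 121 and 48 (adjusted p = 0.28), glutathione S-transferases, 31 and 28 (adjusted p = 0.052), abscisic acid and dehydration genes, 64 and 39 (adjusted p = 0.45), salicylate regulators, 15 and 13 (adjusted p = 0.25), peroxidases, 74 and 23 (adjusted p = 0.089), terpene enzymes, 46 and 22 (adjusted p = 1), and UDP-glycosyltransferases, 112 and 50 (adjusted p = 0.64). Of these, glutathione S-transferases leaned lower with the minimum fold change (adjusted p = 0.021), and peroxidases higher with the similarity column alone (adjusted p = 0.039). Heat shock proteins were 93 higher and 49 lower (adjusted p = 0.83), nitrate genes 50 and 29 (adjusted p = 0.64), sugar and starch genes 66 and 42 (adjusted p = 0.31, or 0.032 at an FDR of 0.01), auxin response genes 97 and 46 (adjusted p = 0.88), senescence genes 31 and 24 (adjusted p = 0.19, or 0.0088 with the reference description alone), carotenoid cleavage and strigolactone genes 4 and 4 (adjusted p = 0.56) and vascular markers 32 and 13 (adjusted p = 0.71). A 13-lipoxygenase of jasmonate synthesis (MtrunR108HiC_019204, scaffold 4) stood at 3.43, chalcone synthase (MtrunR108HiC_019857, scaffold 4), which starts flavonoid synthesis, at 3.61 and a thaumatin-like protein (MtrunR108HiC_002710, scaffold 1) at 3.73 in the authors' deposited table. The lower genes of smallest FDR included glutaredoxin-C11 (MtrunR108HiC_003972, scaffold 1) at -2.83 and 7-deoxyloganetin glucosyltransferase (MtrunR108HiC_026075, scaffold 6) at -2.71, both with FDR 0.00017 in the authors' deposited table. Of the 18 lists past the threshold, 4 were so under every alternative: photosystems, Calvin cycle, cell wall and MAP kinases. Seed and flower markers lost the call only with the reference description alone, which kept 9 of their 202 members. At an FDR of 0.01 the ribosomal protein list leaned to the higher side, with an adjusted p of 0.65.

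Among the 38 lists, that of the cytosolic ribosome differed most between the listings of the comparisons. Of the 153 ribosomal protein genes lower with the connected network, 107 (69.9%) were not listed as lower with the cut network, against 25.4% of the other lower genes (Fisher's exact test, adjusted p = 1.1e-28). This call held under every alternative run. Ubiquitin-40S S27a (MtrunR108HiC_022707), at -3.50 in the authors' deposited table, was 1 of them. The same test was past the threshold for cell wall genes, 50 of 124 (adjusted p = 0.0082), abscisic acid and dehydration genes, 27 of 61 (adjusted p = 0.024), NBS-LRR genes, 47 of 125 (adjusted p = 0.038), and jasmonate synthesis genes, 13 of 25 (adjusted p = 0.041), and each of those calls ended under at least 1 alternative. In the test of genes higher with the cut network alone, 0 of the 38 lists passed an adjusted p of 0.05 by Fisher's exact test, and 4 had an unadjusted p under 0.05. Of these 4, peroxidases and vascular markers had more such genes than the rest, and WRKY factors and P450 genes had fewer. At an FDR of 0.01 the protease inhibitor list passed this test, but 99 of its 202 members matched only by words in different description columns. With words required in 1 column, and at an FDR of 0.05, it had 19 such genes of 58 (Fisher's exact test, adjusted p = 0.77). Whether the call belongs to protease inhibitors is therefore open. Lists chosen after the data were seen are given in the closing part. Absence from a list is not a measured difference, and the difference between the comparisons itself was not tested.

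Among the 15 genes of opposite sign, 12 were lower with the connected and higher with the cut network and 3 the reverse. The authors' deposited table held NDR1/HIN1-like protein 1 (MtrunR108HiC_009105, scaffold 2), of a family with roles in pathogen response, at -1.57 (FDR 0.0053) connected and 2.92 (FDR 0.0095) cut. Allene oxide cyclase (MtrunR108HiC_029243, scaffold 7), a step of jasmonate synthesis, stood at -1.34 (FDR 0.0057) and 2.08 (FDR 0.0082) in the authors' deposited table. The defence marker PR-1 (MtrunR108HiC_038642, scaffold 8) stood at -0.81 (FDR 0.044) and 1.29 (FDR 0.05) in the authors' deposited table. In the other direction, a LysM domain gene (MtrunR108HiC_035065, scaffold 8), a domain that binds chitin-like sugars, stood at 1.87 (FDR 0.019) and -2.33 (FDR 0.0053), and NAC transcription factor 25 (MtrunR108HiC_019250, scaffold 4) at 1.14 (FDR 0.0029) and -1.04 (FDR 0.0055), in the authors' deposited table. At an FDR of 0.01, 3 of the 15 genes were left, and 9 had an absolute log2 fold change of at least 1 in both comparisons.

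**Figure D3:**
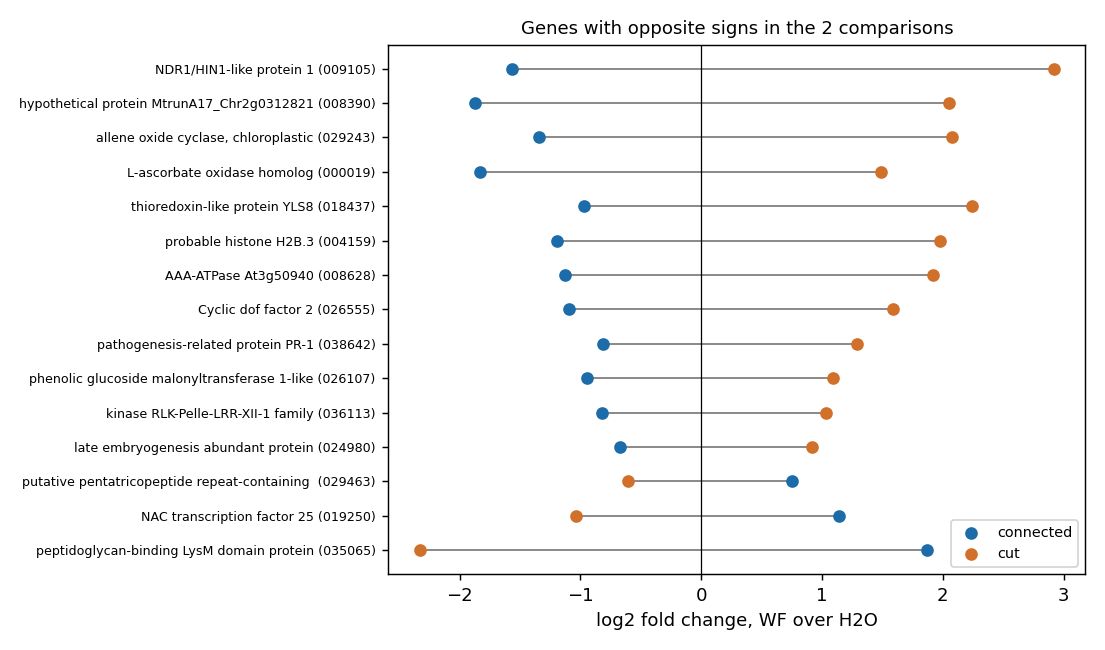
Authors' log2 fold changes (WF over H2O) of the 15 genes whose signs differ, connected network in blue and cut network in orange, joined by a line per gene, with the last digits of the gene ID in parentheses. In 12 genes the connected value lies below 0 and the cut value above it.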

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

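The test of the FDR values in this part was chosen after the result was seen. The 15 genes of opposite sign stand out because the authors' FDR passed 0.05 on one side of 0 with the connected network and on the other side with the cut network, in comparisons that share no library. The difference between the comparisons was not tested, since no values per plant and no standard errors were given. On the log2 scale, the cut minus the connected fold change from the authors' deposited table was 4.49 for NDR1/HIN1-like protein 1, 3.93 for a hypothetical protein (MtrunR108HiC_008390, scaffold 2), 3.42 for allene oxide cyclase and 3.32 for an L-ascorbate oxidase homolog (MtrunR108HiC_000019, scaffold 1). It was 3.21 for the thioredoxin-like YLS8 (MtrunR108HiC_018437, scaffold 4), 3.17 for histone H2B.3 (MtrunR108HiC_004159, scaffold 1), 3.05 for an AAA-ATPase (MtrunR108HiC_008628, scaffold 2) and 2.68 for Cyclic dof factor 2 (MtrunR108HiC_026555, scaffold 6) in the authors' deposited table. Smaller differences in the authors' deposited table were those of PR-1, 2.11, a phenolic glucoside malonyltransferase (MtrunR108HiC_026107, scaffold 6), 2.04, an LRR-XII receptor kinase (MtrunR108HiC_036113, scaffold 8), 1.86, and a late embryogenesis abundant protein (MtrunR108HiC_024980, scaffold 5), 1.58. The difference was negative in the authors' deposited table for the LysM domain gene, -4.20, NAC transcription factor 25, -2.17, and a pentatricopeptide repeat gene (MtrunR108HiC_029463, scaffold 7), -1.36.

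False calls at the FDR threshold are a candidate explanation for these genes. The larger of the 2 FDRs had a median of 0.0267 in them and 0.0129 in genes with the same sign, a difference with a two-sided permutation p of 0.00692. That is what false calls would give, and it does not exclude small real effects, which would also lie near the threshold. If 5% of the genes listed in both were false in 1 comparison with a random sign, 546 opposite genes would be allowed, far above the 15 seen. That share is assumed, since an FDR sets no rate of false calls among genes listed in both. The 546 is a ceiling that any small count meets, so it favours no explanation. An effect of the network on these genes stays open and untested, and 3 of the 15 have both FDRs at or under 0.01.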

How the results depend on the processing

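The minimum absolute log2 fold change of 1 was planned, while the FDR threshold of 0.01 and the other rules for list membership were chosen after the results were seen. No paired analysis was possible because the tables hold group comparisons and no values per library. For the same reason other scalings, filters, tools, sample weights, leaving out libraries, a list test with an estimated correlation between genes and a looser FDR of 0.1 were not run. Depth per library is unknown here, so what depth limits is unknown too.

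At an FDR of 0.01 the cut comparison held 16278 genes, 12446 higher and 3832 lower (76.5% higher, against 66.8% at 0.05). The connected comparison held 18021, 7934 higher and 10087 lower (44.0% higher, against 56.7%), so with the connected network the larger side changed from higher to lower. Both comparisons then shared 8851 genes with the same sign, 5430 higher and 3421 lower, and 3 of opposite sign, while 9167 genes were in the connected comparison alone, 6664 of them lower. A stricter threshold admits fewer genes by construction. With the minimum fold change the genes of opposite sign numbered 9, and the other counts stayed within 1.5 times.

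For the lists, 142 of 152 results kept their side with the minimum fold change, 130 of 151 at an FDR of 0.01, 139 of 152 with the similarity column alone, 123 of 150 with the reference description alone, 150 of 152 with all words within 1 column, either of the 2, and 28 of 36 where genes of other families were taken out of 9 lists. Values below are adjusted p by Fisher's exact test, and "connected lower alone" stands for the test of genes lower with the connected and not with the cut network. With the minimum fold change the calls ended for connected abscisic acid (0.0671) and flavonoid enzymes (0.152), and for connected lower alone of NBS-LRR genes (0.547), abscisic acid (0.0644) and jasmonate synthesis (0.0644). Calls arose for MAP kinases connected (0.0104), WRKY factors connected (0.0373) and cut (0.0359), glutathione S-transferases cut (0.021) and root and nodule markers cut (0.019). The cause was not tested.

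At an FDR of 0.01 the connected calls ended for glutathione S-transferases (0.289), abscisic acid (0.0838), protease inhibitors (0.19) and lectins (0.0515). The cut calls ended for epidermis (0.159), receptor-like kinases (0.496), NBS-LRR genes (0.143), lectins (0.061), ethylene (0.173), P450 (0.0506) and the clock (0.0722). Connected lower alone ended for jasmonate synthesis (0.791), cell wall (0.136) and abscisic acid (0.791). The side turned for ribosomal proteins with the cut network (0.654) and for connected lower alone of NBS-LRR genes (0.644). Calls arose for WRKY factors cut (0.00466), jasmonate synthesis connected (0.0461), TIFY genes connected (0.0271), sugar and starch cut (0.0317) and protease inhibitors in the test of genes higher with the cut network alone (0.0342). The cause was not tested.

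With the similarity column alone the calls ended for connected abscisic acid (0.197), flavonoid enzymes (0.177), glutathione S-transferases (0.215), phosphate (0.0932) and protease inhibitors (0.273), and for cut phenylpropanoid enzymes (0.0729), phosphate (0.0682) and protease inhibitors (0.27). Calls arose for connected lower alone of UDP-glycosyltransferases (0.0351), heat shock proteins (0.0286) and histones (0.0286), and for cut peroxidases (0.0393) and root and nodule markers (0.000628). Protease inhibitors kept 77 of 202 members. Of the 202, 99 matched only by words in different columns, as did 30 of the 689 receptor-like kinases. With all words required within 1 column, the protease inhibitor calls ended with the connected (0.495) and the cut network (0.193), with odds ratios from 1.67 to 1.26 and from 2.00 to 1.52 and fewer genes, and no other call changed.

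Of the 9 lists, 149 of 167 members were taken out of lectins, 135 of 204 of epidermis, 70 of 146 of histones, 51 of 117 of root and nodule markers, 50 of 129 of phosphate and 47 of 202 of seed and flower markers. Taken out too were 11 of 215 of ribosomal proteins, 6 of 22 of TIFY genes and 5 of 22 of the Calvin cycle. The calls ended for lectins connected (0.584) and cut (0.276), phosphate connected (0.177) and cut (0.053) and epidermis connected (0.735) and cut (0.532). They arose for root and nodule markers cut (3.14e-07) and for histones in connected lower alone (0.0265). For lectins the odds ratio did not fall, from 1.57 to 1.72 connected and from 1.98 to 3.24 cut. The intervals for the few lectins left reach below 1, so whether lectins leaned is open. For epidermis it fell from 2.21 to 1.20 and from 2.17 to 1.34, and for phosphate it moved towards 1, from 0.55 to 0.66 and from 0.50 to 0.56, with fewer genes in both lists. The intervals before and after overlap.

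With the reference description alone many lists shrank: ribosomal proteins kept 8 of 215 members, NBS-LRR genes 9 of 427, seed and flower markers 9 of 202, ethylene genes 15 of 201 and clock genes 5 of 21. The side turned for NBS-LRR genes connected (0.518), cut (0.399) and in connected lower alone (adjusted p of 1), for seed and flower markers connected (adjusted p of 1), for jasmonate synthesis in connected lower alone (adjusted p of 1) and for ribosomal proteins cut (0.704). Connected calls ended for ribosomal proteins (0.503), root and nodule markers (0.989), protease inhibitors (0.282), phosphate (0.117), calcium (0.188), the clock (0.111), ethylene (0.97) and lectins (adjusted p of 1). Cut calls ended for seed and flower markers (0.431), P450 (0.334), lectins (0.677), calcium (0.0793), histones (0.335), the clock (0.106) and ethylene (0.933), and connected lower alone ended for abscisic acid (0.237) and cell wall (0.879). Calls arose for pathogenesis-related proteins cut (0.0278), glutathione S-transferases cut (0.00424) and senescence connected (0.00941) and cut (0.00876). The lists that shrank most kept few members, and some of them also turned. With so few members a side can turn by size alone, so size and other causes of the lost calls cannot be told apart. The cause was not tested.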

Other observations

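In this part, the lists and the tests of retroelement genes, of the spread of fold changes, of an offset and of dilution were chosen after the results were seen, while the tests of other organs and of neighbouring genes were set before theirs. Beyond the fixed lists, 12 lists were looked at, with adjustment over those 12. Plastid-type ribosomal proteins were 64 lower and 7 higher with the connected network (Fisher's exact test, adjusted p = 2.4e-16) and 49 and 11 with the cut network (adjusted p = 2.6e-14). Proteasome subunits, which degrade tagged proteins, were 67 lower and 15 higher, then 59 and 16 (adjusted p = 2.2e-12 and 1.6e-15), and autophagy proteins 23 lower and 2 higher, then 23 and 3 (adjusted p = 5.4e-07 and 9.6e-09). Genes described as chloroplastic were 1022 lower and 229 higher, then 823 and 264 (adjusted p = 4.5e-178 and 1.6e-187). Genes described as mitochondrial were 381 lower and 257 higher, then 302 and 308 (adjusted p = 8.8e-17 and 1.5e-16). Ubiquitin, actin and tubulin genes were 145 lower and 92 higher, then 124 and 117 (adjusted p = 4.5e-08 and 7e-09).

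Other families leaned higher. Retroelement-like genes were 838 higher and 53 lower with the connected and 1014 and 48 with the cut network (adjusted p = 2e-143 and 3.7e-120). Genes with no similarity match were 932 higher and 169 lower, then 1192 and 145 (adjusted p = 9.1e-91 and 1.4e-83). Pentatricopeptide repeat genes, which act on organelle RNA, were 351 and 90, then 370 and 70 (adjusted p = 7.5e-24 and 4.8e-16), F-box genes 442 and 160, then 554 and 152 (adjusted p = 2.5e-17 and 9e-12), and MYB factors 240 and 130, then 275 and 103 (adjusted p = 0.0016 and 0.014). NAC factors, 41 higher and 26 lower, then 45 and 26, did not lean past the threshold (adjusted p = 0.54 and 0.53). In the test of genes higher with the cut network alone, genes with no similarity match had more, 414 of 1192 (Fisher's exact test, adjusted p = 5.1e-07). Pentatricopeptide repeat genes had fewer, 53 of 370 (adjusted p = 6.5e-09). In connected lower alone, chloroplastic (adjusted p = 0.004), autophagy (adjusted p = 0.0085) and proteasome genes (adjusted p = 0.03) had fewer.

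Most annotated genes are listed, with retroelement-like genes mostly higher and photosynthesis genes mostly lower. A background of reads over silent genes in WF libraries, such as from genomic DNA, is a candidate explanation. Unspliced RNA and a lower depth of these libraries could not be checked and stay open too. A background over silent genes predicts that genes of other organs are higher more often than other listed genes. For root, nodule, seed and flower markers together, the odds of being higher were 3.37 times those of other listed genes. That is the lower value of the 2 comparisons. Without genes of other families, left out by terms set after the main results were seen, the lower value was 7.30. The odds ratio of 11.1 for retroelement-like genes restates the pattern itself and supports no explanation. Dilution by such a background as the whole cause of the lower genes cannot be told apart from other causes. Among genes listed lower, Calvin cycle and ribosomal protein genes differed in median log2 fold change by -1.96 with the connected network (21 and 153 genes) and by -1.05 with the cut network (19 and 46 genes). That excludes nothing, since dilution lowers a transcript by an amount that depends on its abundance, which the tables do not hold, and since members were picked as lower. Scaling after a fall of abundant transcripts, lifting other genes by 1 factor, stays open: higher genes had an interquartile range of up to 1.05, over the 0.5 set as its limit, but that limit was too low, since the largest standard errors that the FDRs allow would give 1.09. A real release of silent genes after treatment of the sender stays open too, as untested, since both would raise these genes.

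Genes higher in both comparisons had larger fold changes with the cut network. A single scaling offset between the comparisons may add to this. It predicts the same median difference, cut minus connected, for higher and lower genes, and these medians were 0.91 and 0.28, which differ by 0.63. Genes missing from a list could narrow that gap: with every unlisted gene placed to favour the offset it was 0.255, under the limit of 0.3 set for excluding it, so an offset and an effect of the network cannot be told apart here.

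Neighbouring genes tended to share their direction. Of 17747 pairs of consecutive genes with different descriptions in the connected comparison 59.1% had the same direction, against at most 52.2% in 1000 shuffles within scaffolds, and of 18533 pairs in the cut comparison 63.0%, against at most 57.0%. Regions of shared regulation, or of shared background, may underlie this.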
